A study of Cnaphalocrocis medinalis with 6 samples.

How the data were processed

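Small RNA libraries were made from whole-body total RNA of the rice leaf folder, Cnaphalocrocis medinalis, a moth whose larvae feed on rice leaves. Per the labels, the samples were larvae of the instar numbered 5 and pupae, with 3 libraries of each stage. Per the labels' protocols, the libraries were built with the Illumina TruSeq Small RNA kit after TRIzol extraction, with 2 larvae and 2 pupae named for the extraction, and the replicates were described as biological. This was read as 2 animals per library, but the wording does not exclude that the libraries of a stage shared animals, in which case SDs and p-values measure only the spread between these libraries. Groups and replicate numbers were taken from the sample titles.

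The deposited files were output of the miRDeep2 Quantifier, as their names state. Its version, the mapping settings, the genome build and the source of the hairpin set are not given in the sources used here. Each file held 88 rows for 44 hairpin identifiers, each made of a chromosome label and a number and each listed on 2 rows with the same precursor. The rows carried no miRNA name, arm, sequence or coordinates. The 2 rows of a hairpin are called the larger and the smaller row here, by their read count summed over all libraries. The larger row was the first one listed for 41 hairpins and the second for 3. Per the file headers, each file gave the raw read count of its own library, a normalised value, and a read count summed over libraries, which equalled the sum of the 6 library columns in every row. The deposited normalised value was a CPM, the count scaled to the total of the counts in that file, and differed from that quotient by at most 0.005. The larger rows of 2 hairpins were identical in all libraries, and so were the smaller rows of 2 other hairpins, so that the same reads may have been counted on both hairpins of such a pair. Because the identifiers pair with no miRNA names, the 13 lists of miRNAs that had been fixed by name (among them the let-7 complex, muscle and nervous system miRNAs, and plant miRNAs from the diet) matched no row and were not tested. For the same reason at most 2 identifiers that rose and 2 that fell are printed. They are those with the largest fold changes among hairpins past the threshold whose libraries did not overlap between stages. The 4 most abundant hairpins are named as well.

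Library totals ranged from 536524 to 2411261 reads. Over the hairpins tested, the median half-width of the 95% confidence interval of a log2 fold change was 0.54. Intervals and floors given for single counts cover counting error only, since reads without molecular identifiers are not independent molecules.

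Stages were compared on the counts of the larger rows with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3), after filterByExpr and TMM scaling with the file totals as library sizes. The rule of keeping the row with the largest count had been fixed for miRNAs listed on several precursors. The reason given for it, that a read is counted on each precursor, does not apply to rows with the same precursor. The fit had stage as its only term. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. Standard errors were obtained from the fitted coefficient and its F statistic. The ratio of a hairpin's larger to smaller row was tested with limma 3.58.1 on log2((larger count + 1)/(smaller count + 1)) for the 24 hairpins with a mean of at least 10 counts in each row. The design had named this ratio by arm, and the rows took the place of the arms because the files do not name them. Library composition and detection were compared with exact two-sided permutation tests in scipy 1.17.1, in which 3 libraries against 3 cannot give a p below 0.1. Correlations across hairpins were tested with 100000 permutations.

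Both fits were tested on simulated data. For the comparison of stages, 30 simulations on the 44 hairpins recovered 53.9% of hairpins changed 2-fold and 94.2% of those changed 4-fold, and 3.67% of the calls were false. Each simulation changed 10 hairpins, never the most abundant ones, and left all others unchanged. These rates therefore do not cover errors from the choice of scaling. For the row ratio, 98.3% of ratios changed 4-fold were recovered and 2.81% of the calls were false. Those simulations drew the rows independently with the same fixed spread for all, not the spread of the data. Only the larger row was changed, so recovery in the data may be lower.

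Every pair of replicate libraries differed by more than the sampling noise of reads in a chi-square test of its counts (statistic over degrees of freedom 103 to 553), and each library was counted as 1 replicate. This does not show that libraries came from different animals. Alternatives fixed before the data were examined were other scalings (RLE, upper quartile, total counts), DESeq2 1.42.0, limma-voom, other filters, other handling of the 2 rows, the replicate number as a block, and leaving out each library. Thinning of the libraries to 536524 reads was fixed beforehand for the number of hairpins detected, and added after seeing the data for the calls and fold changes. Entering hairpins with identical counts once and the share of the 4 most abundant hairpins were added after seeing the data.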

Results

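The series profiled miRNAs in the whole bodies of the fifth-instar larvae and the pupae of the rice leaf folder, to describe how miRNA abundance differs between these stages. Each stage had 3 libraries. The larval libraries 1 to 3 held 1122959, 958896 and 2411261 reads assigned to miRNA hairpins, and the pupal libraries 785505, 978576 and 536524. The larger rows of the 44 hairpins took 99.7% of all 6793721 reads. Across hairpins, log2 CPM correlated at r = 0.985 to 0.995 between libraries of one stage and at r = 0.947 to 0.979 between libraries of different stages. The first principal component of these values held 73.3% of the variance and separated the 3 larval from the 3 pupal libraries.

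In both stages the same 4 hairpins made up most of the miRNA reads. Chr21_22279 was the most abundant, with 30.6% ± 2.66 (SD, n = 3) of the larger-row reads in larvae and 30.7% ± 1.76 (SD, n = 3) in pupae. Chr10_10335 held 24.4% ± 3.83 in larvae and 21.7% ± 1.14 in pupae. Chr15_13198 held 19.6% ± 1.73 and 20.1% ± 0.0946, and Chr15_12803 held 17.5% ± 0.899 and 17.5% ± 0.231, each in larvae and pupae. Together these hairpins took 92.0% ± 0.822 of the reads in larvae and 90.0% ± 0.494 in pupae, and all 3 larval values lay above all 3 pupal values. That difference reached p = 0.1 in the exact two-sided permutation test, the smallest value the design allows, and 0.5 after adjustment over the 5 composition and detection measures. This set of 4 was chosen after its values were seen. The share of Chr21_22279 alone differed by 0.18 percentage points between stages (exact permutation p = 0.9), and that of the 5 most abundant hairpins by -0.43 points (exact permutation p = 0.6).

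Fold changes here and below are edgeR estimates after TMM scaling, whereas CPM values are scaled to the file totals, so a fold change differs from the quotient of the CPM means beside it. By mean CPM, the fifth most abundant hairpin was not the same in the stages, although the one in this position in pupae also lay above the other in larval libraries 2 and 3. The hairpin in this position in the larval mean had 24950 ± 5219 CPM there and 14403 ± 4274 CPM in pupae (SD, n = 3), a TMM-fitted fall of 1.90-fold (edgeR adjusted p = 0.034). The hairpin in this position in pupae had 24316 ± 2389 CPM in larvae and 40231 ± 3874 CPM in pupae (SD, n = 3), a TMM-fitted rise of 1.50-fold (edgeR adjusted p = 0.010). With upper-quartile scaling its log2 fold change turned to -0.47, and with RLE scaling it was 0.33 (edgeR adjusted p = 0.083). The first of these hairpins lost its call with total counts (edgeR adjusted p = 0.053) and without larval library 1 (0.099), larval library 3 (0.063) or pupal library 3 (0.065). The second also lost its call without larval library 1 (edgeR adjusted p = 0.071), with the replicate block (0.052) and with every row as its own feature (0.40).

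The number of larger rows detected differed by less than the spread between libraries. All 44 larger rows had at least 1 read in every library except pupal library 3, where 43 did. The 1 larger row at 0 there could still stand at up to 5.59 CPM, the level of 3 reads. At least 10 reads were found for 39.7 ± 1.15 larger rows in larvae and 40.0 ± 1.00 in pupae (SD, n = 3, exact permutation p = 1.0). No larger row had 10 or more reads in every library of one stage and 0 in every library of the other.

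Between the stages, 15 of the 40 hairpins tested changed in abundance. In pupae 9 were higher and 6 were lower (edgeR quasi-likelihood test, adjusted p under 0.05), while 25 did not pass the test. The largest fall was that of Chr13_8751, which had 1482 ± 259 CPM in larvae and 222 ± 77.2 CPM in pupae (SD, n = 3), a TMM-fitted fall of 7.32-fold (log2 fold change -2.87, SE 0.28, adjusted p = 0.0012). Chr1_1523 had 1164 ± 136 and 526 ± 69.8 CPM, a TMM-fitted fall of 2.47-fold (log2 fold change -1.31, SE 0.22, edgeR adjusted p = 0.0075). Chr1_1832 had 2526 ± 584 and 8745 ± 1545 CPM, a TMM-fitted rise of 3.17-fold (log2 fold change 1.66, SE 0.20, edgeR adjusted p = 0.0022). Chr16_619 had the largest rise, TMM-fitted at 10.9-fold (log2 fold change 3.45, SE 0.92, edgeR adjusted p = 0.034), but rested on 3 to 10 reads per larval library and 16 to 60 per pupal library, with 5.38 ± 4.66 and 58.0 ± 48.9 CPM (SD, n = 3).

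**Figure D1:**
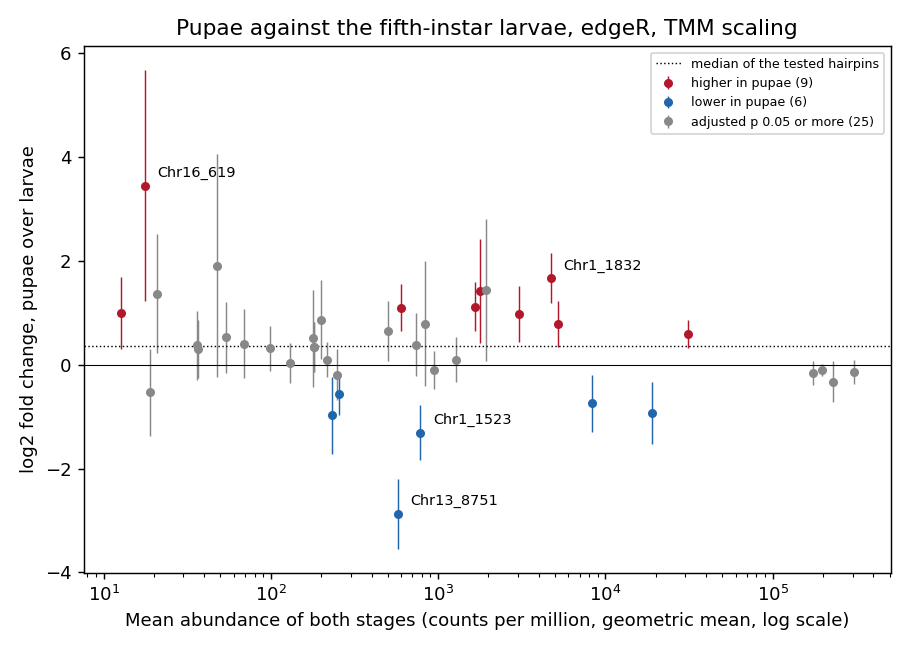
Log2 fold change in pupae over larvae (y axis) against the geometric mean CPM of the stages (x axis, log scale) for the 40 hairpins tested, with 95% confidence intervals as bars and the median of all hairpins (0.36) as a dotted line. The 9 hairpins higher and the 6 lower in pupae are coloured, and the 4 most abundant lie at the right, close to 0.

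Among the 9 hairpins that were higher in pupae, log2 fold changes ran from 0.58 to 3.45, and 5 had at least doubled on the fitted scale. Their mean abundance ran from 13.6 to 32273 CPM. Among the 6 that were lower, the changes ran from -0.57 to -2.87, and 2 of them fell by a log2 value of 1 or more. In CPM scaled to the file totals, all 3 libraries of one stage lay above all 3 of the other for 14 of the 15 called hairpins. The same held for 24 of all 40 tested, or 60%, where chance gives 10% per hairpin. With this scaling the median log2 fold change was 0.50, so a shift common to many hairpins can add to the count. The 24 include the 2 hairpins with identical counts, and a hairpin with a TMM-fitted log2 fold change of only 0.097 (edgeR adjusted p = 0.63). The 4 most abundant hairpins did not pass the test. Their log2 fold changes were -0.14 for Chr21_22279 (95% interval -0.38 to 0.10), -0.33 for Chr10_10335 (-0.73 to 0.06), -0.10 for Chr15_13198 (-0.22 to 0.01) and -0.16 for Chr15_12803 (-0.39 to 0.08). All 4 were lower in pupae past the threshold with RLE scaling, upper-quartile scaling and DESeq2, whereas with total counts Chr21_22279 (0.0069) and Chr15_13198 (0.037) turned positive. Chr10_10335 was also lower past the threshold without larval library 2 (log2 fold change -0.50, edgeR adjusted p = 0.016).

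These directions depend on the scaling. The median log2 fold change of all tested hairpins was 0.36 with TMM, 0.11 with RLE, 0.50 with total counts and -0.73 with upper-quartile factors, and the calls split into 9 higher and 6 lower, 5 and 10, 11 and 2, and 1 and 16 in that order, with 8 and 11 in DESeq2. Relative to the TMM median, Chr16_619 changed by 3.09, Chr1_1832 by 1.31, Chr1_1523 by -1.66 and Chr13_8751 by -3.23 on the log2 scale. Chr13_8751, Chr1_1523 and Chr16_619 passed the test in the same direction under all 4 scalings. Chr1_1832 kept its direction under all 4 and missed the threshold under upper-quartile scaling (log2 fold change 0.56, edgeR adjusted p = 0.10). Upper-quartile factors rest on few hairpins here, among them a hairpin called higher with TMM, so they can absorb part of a rise. Leaving out larval library 1 reduced the calls to 2 higher and 2 lower, and leaving out larval library 3 or pupal library 3 reduced them to 5 and 2, while without pupal library 2 they were 9 and 3. Chr16_619 lost its call without larval library 1, larval library 3, pupal library 1 or pupal library 3 (edgeR adjusted p = 0.054 to 0.095), and its log2 fold change moved to 2.64 without pupal library 3, 2.85 without larval library 3 and 4.26 without larval library 2. Chr13_8751 and Chr1_1523 passed the test in every alternative run, with 1 draw used for thinning.

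**Figure D2:**
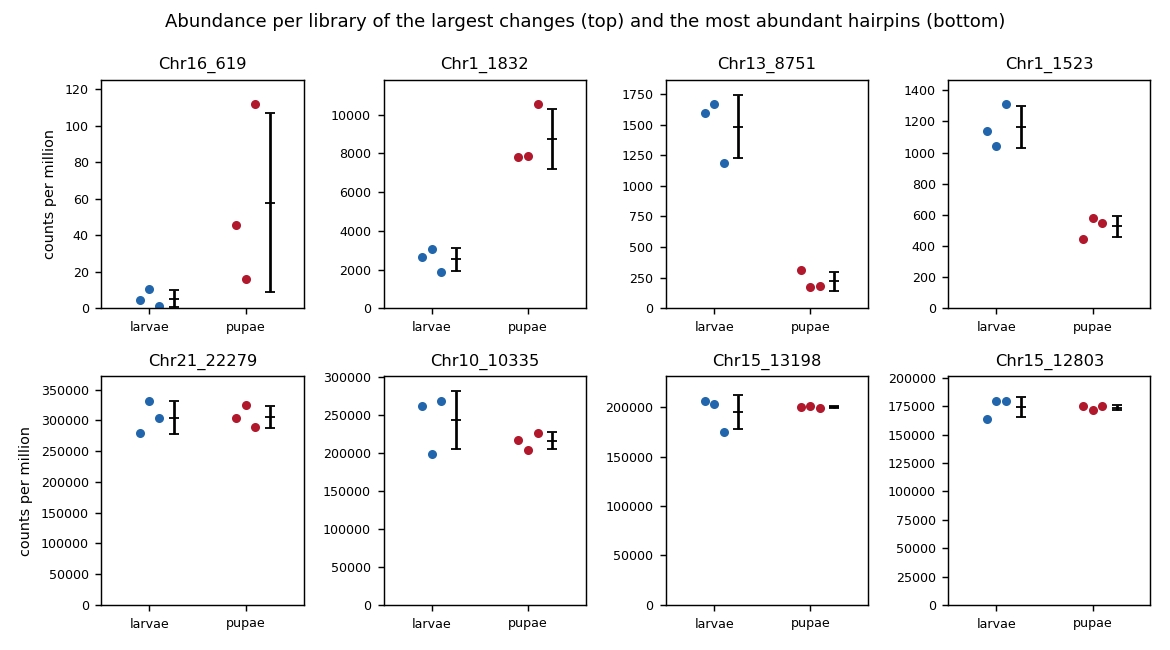
CPM of each library (y axes from 0) for the 4 hairpins with the largest changes, in the top row, and for the 4 most abundant, in the bottom row; black marks are the mean ± SD of the 3 libraries per stage. Larval and pupal libraries do not overlap for the hairpins of the top row, which were chosen by this rule, and do for those of the bottom row.

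With every row entered as its own feature, both rows of 23 hairpins could be tested. The log2 fold changes of the larger and the smaller row correlated at r = 0.85 across these hairpins (permutation p = 1e-05, the smallest that 100000 permutations can give) and at rho = 0.72 (permutation p = 0.00015). The sign was the same in 17 of the 23, and 2 of the 23 smaller rows passed the test. Hairpins are not independent replicates. Without the 2 hairpins farthest from the median the correlation was 0.71 (permutation p = 0.00028). In Chr13_8751 both rows fell, with log2 fold changes of -3.05 and -2.78 (edgeR adjusted p = 0.00011 and 0.036). In Chr1_1832 the larger row rose by 1.50 (edgeR adjusted p = 0.0057), while the smaller row had a log2 fold change of 0.93 (edgeR adjusted p = 0.20). The larger row of Chr1_1523 had a log2 fold change of -1.55 (edgeR adjusted p = 0.019) and its smaller row -0.78 (edgeR adjusted p = 0.11). The smaller row of Chr16_619 was not tested.

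The ratio of the larger to the smaller row of a hairpin did not pass the test for any of the 24 hairpins with enough reads (limma, smallest adjusted p = 0.14), and 4 had an unadjusted p below 0.05. The largest change in this ratio was 1.13 on the log2 scale, in a hairpin that was higher in pupae. The median half-width of the unadjusted 95% interval was 0.75. The adjusted test did not call even the change of 1.13, so changes larger than 0.75 could also go undetected. With a pseudocount of 5, or without pupal library 3, 2 ratios passed the threshold, and 1 did among hairpins with at least 50 reads in each row on average.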

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

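The number of hairpins higher in pupae was 9, and moved by over 1.5 times to 5 with RLE factors, 1 with upper-quartile factors, 3 with every row as its own feature and 4 with the replicate block. The number lower was 6, and moved to 10 with RLE factors, 2 with total counts, 16 with upper-quartile factors, 11 with DESeq2 and 3 with the replicate block. No sign of pairing by replicate number was seen: the deviations of same-numbered libraries correlated at -0.02, -0.10 and -0.27, and 0 of 6 libraries correlated best with their own number. With 3 libraries per stage, this cannot exclude pairing. Leaving out one library gave 2 to 9 hairpins higher and 2 to 7 lower, on fewer samples. Of the 15 calls, limma-voom kept 13, DESeq2 and the summed rows 14 each, RLE and total counts 11 each, upper-quartile factors 7, and the rows as separate features and the replicate block 6 each. Leaving out larval library 1 kept 4, and leaving out any other library 7 to 13. Dropping the most abundant hairpin, the filter or identical hairpins kept all 15. The fitted direction reversed for Chr21_22279 (0.0069) and Chr15_13198 (0.037) with total counts, and for the hairpin that was the fifth most abundant in pupae (-0.47) with upper-quartile factors, since a scaling shifts all hairpins by one amount. Alternative fold changes cover 10 hairpins: the 4 with the largest changes, the 4 most abundant and the fifth most abundant of each stage. Of these values, 158 of 188 kept direction and side of the threshold. Ratios of the 2 rows past the threshold numbered 2 with a pseudocount of 5 and 1 with at least 50 counts, and 0 to 2 when one library was left out; the cause was not tested. The difference in the share of the most abundant hairpin (0.18 percentage points) ran from -1.11 (without larval library 1) to 1.55, with -0.75 without pupal library 2. That of the 5 most abundant (-0.43) ran from -0.82 to 0.022, the latter without pupal library 3, and that of the 4 most abundant (-2.03) from -2.35 to -1.56. The difference in detected larger rows (-0.33) was 0.33 at 10 counts or more and -0.28 in thinned libraries (exact permutation p = 0.3), and ran from -0.50 to 0 without one library. The exact permutation test used for these differences cannot pass 0.05 with 3 libraries against 3. Tests of the fixed miRNA lists by camera and fry were not run, since no row could be matched to a miRNA name.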

Other observations

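The thinning of the calls and the tests on near numbers, on the share of the most abundant hairpin and on larval library 2 were chosen only after the results had been seen, and the criteria for reading the splits and the scalings were also set after seeing them. Hairpins whose identifiers share a chromosome label and have numbers no more than 20 apart had log2 fold changes that lay closer together than those of permuted hairpins, and of the 14 hairpins in such pairs only 3 passed the test. Those were Chr1_1832 and 2 hairpins numbered near it. With TMM scaling all 3 rose in pupae, by log2 fold changes of 1.66, 0.97 and 1.41 (edgeR adjusted p = 0.0022, 0.022 and 0.040). Of the 9 higher calls only 4 kept their direction under all 4 scalings, so the joint rise may depend on the scaling. Over the 10 such pairs among the tested hairpins, the mean absolute difference of log2 fold changes was 0.32, against 1.10 for permuted hairpins (one-sided permutation p = 0.00046). Identical rows counted on both hairpins of a pair do not account for the whole pattern. With hairpins that share an identical row entered once, the difference was 0.37 against 1.14 (permutation p = 0.00429). It was 0.30 over 4 pairs when the 3 hairpins that all rose were left out as well (permutation p = 0.00993). None of the hairpins in these 4 pairs passed the test between stages. Hairpins with little change can lie close together without changing jointly, so this value does not show a joint change. The same limit holds in part for the tests that include the 3 hairpins that rose. For those 3 hairpins a candidate explanation is joint transcription of neighbouring hairpins, but the files give no coordinates. Whether near numbers mean near loci, and whether reads are shared in part between similar hairpins, stays open.

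The calls between stages were weighed against technical explanations. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave 15 or more calls, and the highest of the other splits gave 0. The splits are too few for a share under 0.05. All other splits also mix larval and pupal libraries within a group. A stage difference then widens the spread within groups and lowers the number of calls there. For the row ratios the real split gave 0 calls and the highest other split 1; a real count of 0 is necessarily matched by all 10 splits, so this comparison shows nothing. The tables argue against unequal counting depth as the whole cause, since thinning every library to the smallest total left a median of 13.5 calls over 20 draws (6 to 16). They also argue against a scaling set by the most abundant hairpin alone, whose share was nearly equal in larvae (30.6%) and pupae (30.7%). Between any larval and any pupal library, this share would shift the log2 CPM of all others by at most 0.095. That lies below the smallest absolute log2 fold change among the calls (0.57). The 4 most abundant hairpins together were not tested in this way. Their joint share was 92.0% in larvae and 90.0% in pupae, so the other hairpins together held a larger share in pupae. How far this reaches the calls stays open. The choice of scaling stays open for the balance of higher and lower calls. Under TMM, RLE and total counts, 7 of the 15 kept their call (5 higher, 2 lower). When upper-quartile factors were added, 3 did (1 higher, 2 lower), while 10 kept their direction under all 4. The upper quartile of a library rests here on few hairpins. In every library 1 of them was a hairpin called higher, with a mean of 2075 CPM in larvae and 4425 CPM in pupae. Upper-quartile factors can thus absorb part of the rises, so their split is not independent of the hairpins that rose. Of the 3 that kept their call under all 4 scalings, Chr13_8751 and Chr1_1523 also passed in every other alternative. For thinning, single hairpins were read from 1 of the 20 draws, with a number of calls near the median. Chr16_619 missed the threshold in 5 of 18 alternatives and was not tested in that draw. A difference between larvae and pupae stays among the open explanations.

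Larval library 2 lay towards the pupae. Across the 40 tested hairpins, the difference of larval library 2 and larval library 1 in log2(CPM + 2) correlated with pupae minus larval library 3, which shares no library with it, at r = 0.51 (permutation p = 0.00237) and rho = 0.34 (permutation p = 0.0304). Without the 2 hairpins farthest from the median r was 0.18 (permutation p = 0.29), so this relation rests on those hairpins, and a difference in age between the larvae sampled could be its source but is not settled by this test. Library 2 against library 3 gave r = 0.58 (permutation p = 0.00034) and rho = 0.32 (permutation p = 0.043) with pupae minus library 1, and r = 0.49 (permutation p = 0.00212) and rho = 0.31 (permutation p = 0.0595) without its own 2 farthest hairpins. Larval library 3 was 2.15 times as deep as library 1, and library 2 0.854 times, yet 3 against 1 gave only r = -0.14 with pupae minus library 2 (permutation p = 0.376). Its absolute r was smaller by 0.37 than that of 2 against 1 (bootstrap 95% interval -0.07 to 0.65), so depth cannot be told apart from other differences here, because the interval includes 0.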
